A study of Mus musculus with 2 samples.

How the data were processed

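Neuronal nuclei of mouse hippocampus were sorted by flow cytometry after perfusion and homogenisation and run on 10x Chromium V2, per the labels' protocols. There were 2 groups of 1 library each, a control (1 male and 1 female wild-type mouse pooled) and an IL-33 enriched library (labelled as 1 female Il33-H2B-mCherry heterozygote), assigned from the sample titles. Per the labels, the raw data of the enriched library held male and female nuclei and the female, Xist-positive ones carried the reporter. These labels do not settle whether a male animal was also in the library, and its nuclei were treated as 1 group. How nuclei were chosen for the deposited file is not given in the sources used here. Every nucleus in it had at least 2 Xist UMIs, and 32.5% had a UMI of a Y-linked gene, against 41.0% in the control.

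Cell Ranger 2.1, STAR, Seurat 2.3.4 and the build mm10 (GRCm38) are named in the submitters' processing notes, with no role or order. The deposited values of each library are natural log values, the log of 1 plus the UMIs of a gene per 10000 UMIs of the nucleus, as the values themselves showed. Whole UMI counts were computed back from these deposited natural log values by dividing by the smallest step of each nucleus. In both libraries 100% of nonzero values lay within 0.01 of a whole number, and genes left out of the files held 0.00682% of UMIs in the control and 0.00909% in the enriched library. The planned analysis had assumed deposited counts, so the recovered counts were used in its place and both scaling alternatives were coded directly. A table of both libraries together holds centred and scaled score values that the authors deposited for 4460 genes and 11879 nuclei. Of its values 91.04% were below 0, and 4366 of its genes were a straight line of the log values, so it served only to check that it held the same nuclei. Each library file listed 19089 genes, of which 18351 symbols matched GENCODE release M21 (GRCm38), the source of all coordinates.

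Nuclei needed at least 200 genes and under 5% mitochondrial UMIs. All deposited nuclei passed, since the files had been filtered to at least 1001 genes a nucleus. Doublets were called per library with Scrublet in scanpy 1.11.5 and left out. They were 328 control nuclei (3.04%, 95% interval 2.72 to 3.38) and 5 enriched nuclei (0.463%, 0.151 to 1.08). The planned restriction of the enriched library to Xist-positive nuclei applied only if the file held nuclei without Xist, which it did not, so all its nuclei were kept.

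Nuclei of both libraries were clustered together on log-normalised counts of 2000 variable genes without Il33, sex-linked and mitochondrial genes, 30 principal components, 15 neighbours and Leiden resolution 0.8, which gave 19 clusters. A cluster was named for a class when at least 3 of its fixed markers were 2-fold or more above the other nuclei, more than for any other class, and no other class had more markers among its top 10 genes. Fold for this step used a pseudocount of 20 CPM and genes with at least 20 counts. Classes with at least 50 nuclei in each library were compared. CA1 pyramidal-like clusters were led by Galntl6, Pde11a and C1qtnf7, the CA3 cluster by Trps1 and Ccbe1, the CA2 cluster by Strip2 and Ccdc3, interneuron-like clusters by Nxph1, Npas3 and Fgf13, subiculum and deep cortical-like clusters by Fn1, Vwc2l and Foxp2, and unnamed clusters by Pdzrn3, L3mbtl4, St18, Csf2rb2 and Lhfpl3. Granule-like cluster 2 was also compared by itself, a choice made after the data were seen, with its named genes taken by the rule for another class.

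Within a class, UMIs were summed per library and divided by the class total and put on the CPM scale. The floor was 20 expected counts in the shallower library at the mean of both CPM values, which was 8.18 CPM for granule-like nuclei and 38.7 CPM for CA1 pyramidal-like nuclei. Genes were counted as higher or lower at a ratio of 1.5 or more. Shares have exact Clopper-Pearson 95% intervals, sums exact Poisson intervals and ratios the exact conditional binomial interval, and a share of 0 is limited by 3 counts. Xist, Tsix and 7 Y-linked genes were left out of the gene counts because the libraries differ in sex. The control's mice were approximated by nuclei with Xist and no Y-linked UMI (1637 granule-like) and nuclei with a Y-linked and no Xist UMI (618). That split leaves out nuclei with neither and nuclei with both. Of control nuclei with 6 or more Xist UMIs, 21.3% had a Y-linked UMI, so the parts may not separate the mice cleanly.

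Before the data were examined, 27 gene lists, the class markers and the rule for named genes were fixed. The rule took, among genes above the floor that differed in the same direction from both parts of the control, the 12 highest and 12 lowest log2 ratios in granule-like nuclei and the 3 highest and 3 lowest in another class, and up to 2 members at each end of a list. It left out sex-linked, mitochondrial and ribosomal protein genes and unnamed gene models, except as list members. Nr4a3, Jun, Mfsd4, Ntng1, Eif2s3y, Ddx3y, Tnr, Adamts9 within cluster 2 and the named genes read again there fall outside it and were chosen after their values were seen. A list's median log2 ratio needed at least 3 members above the floor and was placed among 10000 random lists of the same size, each member drawn from the 50 genes nearest in mean expression. The percentile describes these libraries and is not a test. The lists were immediate early genes, late activity-regulated effectors, synaptic vesicle release, postsynaptic density and CaMK signalling, glutamate receptors, GABA and glycine receptors, potassium channels, sodium and calcium channels, extracellular matrix, matrix proteases, axon guidance and adhesion, neurexins, immature and mature granule cell genes, trophic factors, interferon, heat shock, chromatin regulators, IL-33 and its receptor, sex-linked genes, ribosomal protein and mitochondrial genes, and markers of astrocytes, oligodendrocytes, microglia, interneurons and CA pyramidal cells. A few genes that the rule took are not reported here and were left out of the named genes without replacement. Ntng1 stood in both the mature granule and axon guidance lists, Erbb4 in the interneuron and trophic lists and Gpc5 in the astrocyte and matrix lists. Il1rl1, the other IL-33 receptor gene, was not analysed here.

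The ratio step was tested on simulated granule-like counts with 200 genes changed by known folds, in which 8164 genes passed the floor. The interval held the true ratio for 95.8% of genes, and 150 unchanged genes passed the 1.5-fold rule. Of genes changed 1.5-fold, 18 of 40 passed it. All 40 changed 2-fold and all 40 changed 3-fold passed, with median estimates of 2.00 and 3.00. Of genes changed 0.5-fold, 36 of 38 passed, and of those changed 0.667-fold, 18 of 34. Counting noise and the cluster mix were each simulated in 100 draws at the real depths, noise for each compared set and for the parts of the control.

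Alternatives fixed beforehand were another nucleus filter, each part of the control, no doublet removal, resolutions 0.4 and 1.5, clusters made from the control alone, equal weight per nucleus, thinning to 1700 UMIs, TMM and median-of-ratios scaling, a floor of 50, no floor and a 2-fold rule. Those added after seeing the data were at least 1500 genes a nucleus, at least 3 Xist UMIs in enriched nuclei, at least 4 Xist UMIs in both libraries, Xist with no Y-linked UMI in both, and control granule-like clusters weighted as in the enriched library. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.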

Results

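Nuclear RNA of hippocampal neurons was profiled from C57/Bl6 mice at postnatal day 75, with droplet libraries in which each RNA molecule carries a unique molecular identifier (UMI). The control library held sorted neuronal nuclei of 2 wild-type mice, 1 male and 1 female. The IL-33 enriched library is labelled as 1 female heterozygous for Il33-H2B-mCherry, a fluorescent nuclear reporter of the cytokine gene Il33, whose female nuclei carried the reporter signal. Its labels also say that the raw data held male nuclei, so which animals gave the nuclei used is not settled by them. Each group had 1 library, so there were no replicates, no difference between groups could be tested, and the 95% intervals given cover counting error only. The control file listed 10800 nuclei with 42183289 UMIs, between 1746 and 7998 a nucleus. The enriched file listed 1079 nuclei with 3650504 UMIs, between 1726 and 7992 a nucleus. After predicted doublets were left out, 10472 control nuclei (median 3503 UMIs) and 1074 enriched nuclei (median 2971 UMIs) were compared.

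The transcript of the sorted gene was compared between the libraries, since it checks their labels. Il33 (ENSMUSG00000024810, protein-coding, plus strand of chromosome 19, 29925114 to 29960718 in GRCm38) encodes a nuclear cytokine released as an alarm signal. It reached 13.8 CPM (share of all UMIs on the usual CPM scale; 95% interval 10.2 to 18.2; 50 UMIs) in the enriched library and 3.21 CPM (2.68 to 3.81; 129 UMIs) in the control, a ratio of 4.31 (3.04 to 6.01). Within dentate granule-like nuclei it was 13.9 CPM (9.64 to 19.4) against 5.58 CPM (4.19 to 7.27), a ratio of 2.5 (1.58 to 3.90). The ratio was 2.29 (1.35 to 3.92) against the Xist-positive part of the control alone, with 28 control UMIs, and 4.02 (1.67 to 11.7) against its Y-positive part, with only 6. In CA1 pyramidal-like nuclei 4 enriched and 21 control UMIs gave a ratio of 3.71 with an interval of 0.927 to 11, so a difference was not detectable there at this depth. Over all nuclei outside the granule-like class Il33 was 13.6 CPM (7.75 to 22.0; 16 UMIs) against 2.45 CPM (1.93 to 3.08; 75 UMIs), a ratio of 5.53 (3.01 to 9.57), so the difference was not particular to granule-like nuclei. The ratio was 4.40 (1.43 to 11.6) in unnamed clusters, from 6 enriched UMIs, and 30.9 (2.94 to 189) in GABA interneuron-like nuclei, from 2.

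The Il33 difference within the granule-like class went with the class's clusters, numbered 1 and 2. In cluster 2, Il33 was 14.6 CPM (9.96 to 20.6) in the enriched library and 12.8 CPM (8.85 to 17.9) in the control. In cluster 1 it was 8.10 CPM from 2 UMIs (0.981 to 29.3) and 2.85 CPM (1.74 to 4.40), respectively. With the control's clusters weighted as in the enriched library, a setting chosen after the data were seen, Il33 in control granule-like nuclei was 11.8 CPM and the ratio 1.18. An Il33 UMI was seen in 3.60% (2.44 to 5.10) of enriched and 1.39% (1.03 to 1.84) of control granule-like nuclei, at median depths of 2788 and 2671 UMIs. In the control, GABA interneuron-like nuclei, taken as the background, had a share of 0.424% (0.138 to 0.987) at a median of 3555 UMIs. In the enriched library they had 1 of 11 nuclei with a UMI (9.09%, 0.230 to 41.3). All enriched nuclei outside the granule-like class had 5.83% (3.23 to 9.59) at a median of 4966.5 UMIs. These came through the same sort and were deeper than the granule-like ones, so they give no background. The enriched granule-like share was therefore neither shown nor excluded to lie above one. With each nucleus thinned to 1700 UMIs, the shares were 2.28% in enriched and 0.926% in control granule-like nuclei and 0.0848% in control GABA interneuron-like nuclei.

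**Figure D1:**
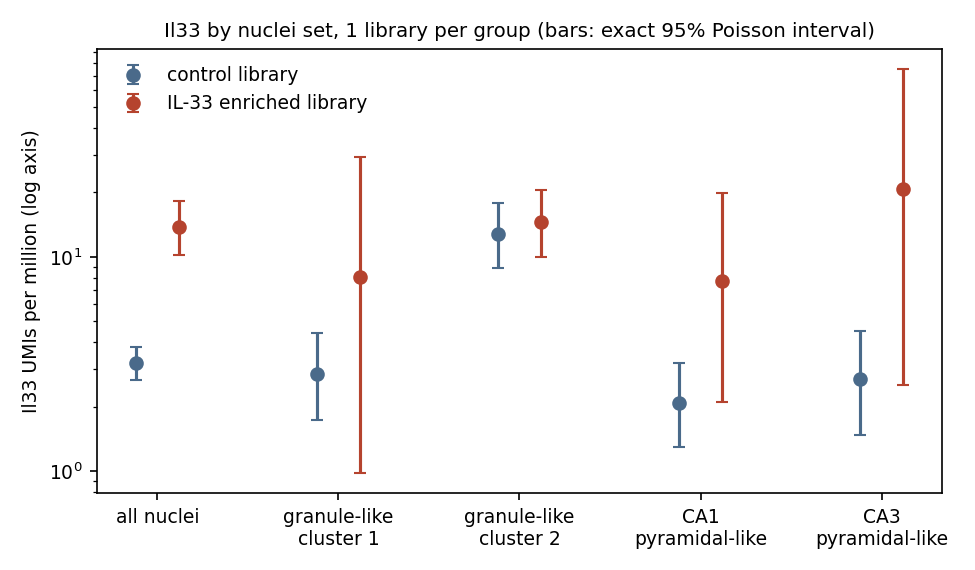
Il33 level (CPM, log axis) in all nuclei, in both granule-like clusters and in the CA1 and CA3 pyramidal-like classes, for the control and IL-33 enriched libraries, with bars for the exact 95% Poisson interval. In granule-like cluster 2 the values of 14.6 and 12.8 CPM lie close together, and over all nuclei 13.8 stands above 3.21 CPM.

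The classes of neurons collected in each library were compared next. Nuclei of both libraries were sorted, and the enrichment for IL-33 that the labels name can set such shares. Dentate granule-like nuclei, the principal neurons of the dentate gyrus, made up 77.7% (75 to 80.1) of the enriched library and 33.0% (32.1 to 33.9) of the control. CA1 pyramidal-like nuclei were 8.75% (7.13 to 10.6) against 21.1% (20.3 to 21.9), and CA3 pyramidal-like nuclei 1.86% (1.14 to 2.86) against 9.0% (8.46 to 9.57). GABA interneuron-like nuclei were 1.02% (0.512 to 1.83) against 11.3% (10.7 to 11.9), and subiculum and deep cortical-like nuclei 2.24% (1.44 to 3.31) against 11.6% (11 to 12.2). CA2 pyramidal-like nuclei were 1.03% (0.847 to 1.24) of the control and 0 of 1074 in the enriched library. That allows a share of up to 0.343% by the exact interval used for the other classes, or 0.279% by the limit of 3 counts. A small astrocyte-like cluster, whose leading genes also held Cpa6 and Mob3b, was 0.466% (0.151 to 1.08) against 1.09% (0.899 to 1.31). Clusters that matched no class held 8.01% (6.46 to 9.80) and 11.9% (11.3 to 12.6). Among nuclei with at least 1500 genes the granule-like share was 56.1% in the enriched library and 11.3% in the control.

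The granule-like class was split unequally between its clusters. Cluster 2 held 755 of the 834 enriched granule-like nuclei and 942 of the 3457 control ones, and cluster 1 held 79 and 2515. Cluster 2 was led by Pde7b, Glis3, Trpm3 and Ano2, and cluster 1 by Stxbp6, Slc4a4 and Plcl1. Ano2 and Cdh13, which were among the leading genes of cluster 2, also differed between the libraries. Values within the class therefore compare mostly cluster 2 with mostly cluster 1, and the comparison within cluster 2 was added after the data were seen.

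**Figure D2:**
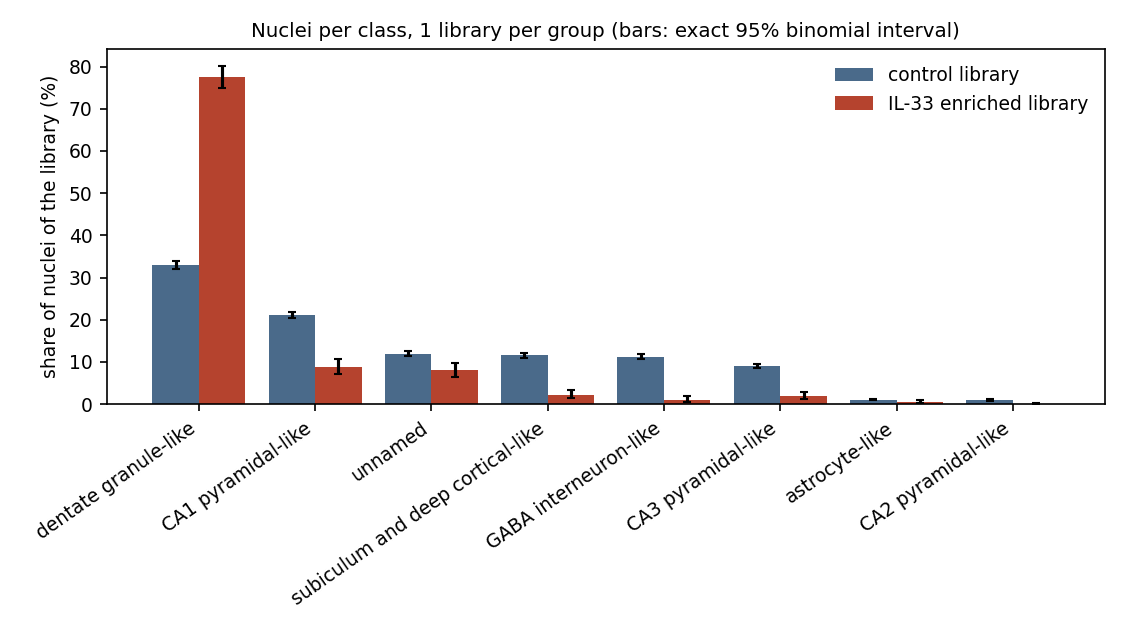
Share of nuclei (%) in each class for the control and IL-33 enriched libraries, with bars for the exact 95% binomial interval. Dentate granule-like nuclei are 33.0% of the control and 77.7% of the enriched library, and every other class has a lower share in the enriched library, with overlapping intervals for astrocyte-like nuclei.

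Granule-like nuclei of the IL-33 enriched library were compared with those of the control. The control was not selected for Il33 and also held granule-like nuclei with Il33 UMIs. The comparison is thus between libraries and does not set reporter-positive neurons against reporter-negative ones. Tacr1, the substance P receptor (plus strand of chromosome 6, 82402334 to 82560104), was at 21.7 CPM against 3.61, a ratio of 6.0 (3.84 to 9.48). It rests on 53 enriched and 35 control UMIs. P2rx5, an ATP-gated ion channel, had a ratio of 4.88 (3.13 to 7.64), and Ano2, a calcium-activated chloride channel, one of 3.85 (3.24 to 4.57). Otof, a calcium sensor of vesicle fusion (minus strand of chromosome 5, 30367062 to 30461932), had a ratio of 4.74 (3.56 to 6.32). The matrix genes Ecm2 and Col23a1, a transmembrane collagen (plus strand of chromosome 11, 51289920 to 51583918), had ratios of 3.96 (3.04 to 5.17) and 3.68 (3.20 to 4.22).

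Other genes at the top of the ranking had ratios between 3.33 and 3.86. They were Casq1, a calcium-binding protein of intracellular stores, Slc38a11, Nr2f2, which encodes the transcription factor COUP-TFII, the endolysosomal channel gene Tpcn2, the cadherin gene Cdh4, and Tcerg1l. The gene furthest below the control was Dsp, which encodes the junction protein desmoplakin (plus strand of chromosome 13, 38151294 to 38198577). It was at 10.2 CPM against 40.1, a log2 ratio of -1.97 (-2.62 to -1.39). Svil, an actin-binding protein gene, followed at -1.80 (-2.60 to -1.09), and Syndig1, whose product associates with AMPA receptors at synapses (plus strand of chromosome 2, 149829211 to 150004392), at -1.71 (-2.04 to -1.40). The lactase gene Lct was at -1.45 (-1.98 to -0.96). The actin-binding gene Cotl1, Nudt5, Mpp7, the adhesion gene Clmp, the cytokine gene Il16, Mkks and Crispld1 lay between -1.41 and -1.18. In the control, Tacr1, P2rx5, Casq1, Slc38a11, Nr2f2 and Tpcn2 were below 8.18 CPM, so they passed the floor through their enriched value. Svil, Cotl1, Nudt5, Mpp7, Mkks and Crispld1 were below it in the enriched library and passed through the control. The intervals do not allow for picking the extremes of the ranking.

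Of these 23 genes, 21 differed in the same direction between cluster 2 and the other granule-like nuclei inside the control library. Most enriched nuclei of the class are those of cluster 2, so values of these genes within cluster 2 are partly set by how the genes were picked. The 12 higher genes had log2 ratios from 1.74 to 2.59 in the class and from 0.63 to 2.17 within cluster 2. Tacr1 at 2.17 (1.30 to 3.14), Casq1 at 1.58 (0.68 to 2.55) and Tpcn2 at 1.33 (0.65 to 2.03) were the highest there. P2rx5 was at 1.05 (0.35 to 1.78) against 2.29 in the class, Otof at 1.18 (0.70 to 1.68) against 2.25, Ecm2 at 0.93 (0.49 to 1.37) against 1.99, Ano2 at 0.79 (0.51 to 1.07) against 1.94, Col23a1 at 1.03 (0.79 to 1.27) against 1.88 and Nr2f2 at 0.63 (0.00 to 1.26) against 1.83. Of the 21 genes with a value there, 18 had an interval that left out no change. Dsp lay at a log2 ratio of -1.20 (-2.04 to -0.42). Nudt5 at -1.27, Cotl1 at -1.24, Mkks at -1.03 and Il16 at -0.96 also had intervals wholly on the lower side. Syndig1 at -0.31 (-0.77 to 0.14), Lct at -0.23 (-1.04 to 0.57) and Clmp at 0.62 (-0.17 to 1.42) did not differ detectably there. Rela, a subunit of NF-kB, was among the highest within cluster 2, at 3.17 times the control (1.63 to 6.54). Zbtb41 at -1.43 (-2.56 to -0.43), Ndufa12 at -1.41 (-2.39 to -0.52) and Crispld1 at -1.35 (-2.37 to -0.41) were the lowest. They rest on 11, 14 and 13 enriched UMIs, and the intervals do not allow for picking the extremes. Of lower genes 196 were counted within cluster 2, where counting noise alone gave a median of 166 and at most 188.

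**Figure D3:**
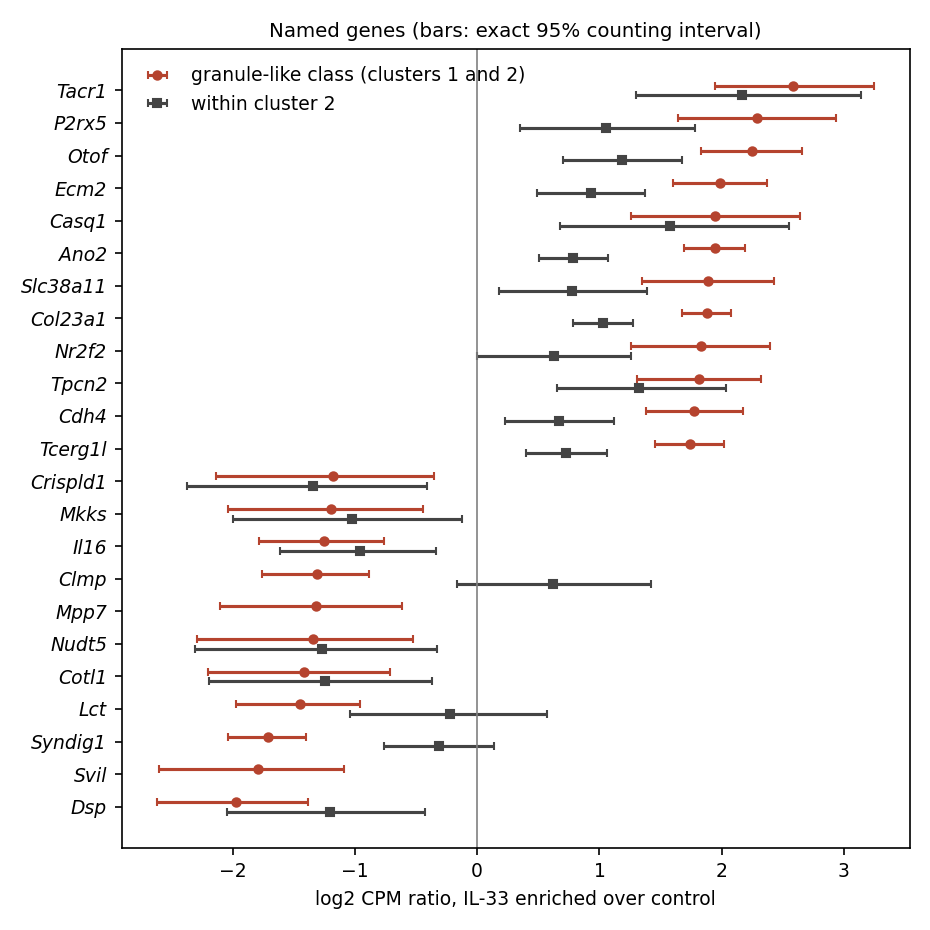
Log2 CPM ratio (IL-33 enriched over control) of the 23 named genes in the granule-like class and, for all but Svil and Mpp7, which had no value there, within granule-like cluster 2, with bars for the exact 95% counting interval. Tacr1 is the highest in both, at 2.59 and 2.17, while Clmp lies at -1.31 in the class and at 0.62 within cluster 2.

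Among 8269 genes above the floor in granule-like nuclei, 589 were at least 1.5-fold higher and 201 at least 1.5-fold lower in the enriched library, out of 2443623 and 9686154 UMIs. The median gene lay at a log2 ratio of 0.07. With TMM scaling, which lowers log2 ratios by 0.13, the split was 343 higher and 409 lower, and with median-of-ratios scaling, with a like shift, 336 and 416. In simulations with no difference between libraries, counting noise alone gave a median of 67.5 genes higher and 82 lower. With only the control's clusters mixed as in the enriched library, it gave 242 and 160. The Xist-positive and Y-positive parts of the control, which stand only roughly for its 2 mice, differed by that size at 247 and 224 genes. Counting noise at their lower depth gave 259 and 158. Both parts come from the same library and may hold nuclei of either mouse, so these counts do not measure the difference between mice. Within cluster 2, 419 genes were higher and 196 lower in the enriched library, against 159 and 166 from counting noise. The parts of the control differed there at 851 and 741 genes, from 1289909 and 503570 UMIs, against 884 and 675 from counting noise.

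Immediate early genes, which neurons switch on within minutes of activity, were higher as a list. Of 6 members above the floor, 4 were at least 1.5-fold higher and 0 lower, and the median log2 ratio of 0.67 lay at percentile 99.64 of random lists matched on mean expression. Npas4 was at 1.40 (0.71 to 2.08), Nr4a1 at 0.94 (0.23 to 1.61), and Nr4a3 at 0.68 (0.26 to 1.09) and Jun at 0.65 (0.15 to 1.13), the last pair named after their values were seen. Within cluster 2 only 4 members passed the floor, 2 of them higher and 0 lower, with a median of 0.33 at percentile 79.74. Summed UMIs of all members were 1.55 times as high in granule-like nuclei (1.36 to 1.75), 1.43 times within cluster 2 (1.21 to 1.69) and 1.40 times in CA1 pyramidal-like nuclei (1.17 to 1.67). Late activity-regulated effectors had 1 of 11 members higher, the vesicle protein gene Sv2c at 0.62 (0.41 to 0.83), and a median of 0.18 at percentile 87.68, and within cluster 2 had 0 past 1.5-fold.

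Genes of mature granule cells were lower as a list, with 4 of 12 members at least 1.5-fold lower, 1 higher, and a median log2 ratio of -0.49 at percentile 0.0. Besides Dsp and Lct, the transporter gene Mfsd4 was at -1.14 (-1.50 to -0.80) and Ntng1, a netrin family gene, at -0.81 (-0.92 to -0.71), both named after their values were seen. Ntng1 was also in the axon guidance list. Plk5 was at 0.62 (0.28 to 0.95). Dsp, Lct, Plk5 and Tdo2 in this list were also among the fixed markers of the class. Of these, Dsp and Lct counted in naming cluster 1, and none counted in naming cluster 2. Inside the control, Dsp and Lct were also lower in cluster 2 than in other granule-like nuclei, at -1.26 and -2.03. Whether the nuclei differed in maturity was not tested. Within cluster 2 the list had 1 member higher and 1 lower, and its median was -0.15 at percentile 2.33. Immature granule cell genes had a median of 0.00 at percentile 38.97, with Dpysl3 at 0.75 (0.39 to 1.10) as the 1 of 7 members that was higher, and 0 past 1.5-fold within cluster 2.

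Axon guidance and cell adhesion genes had 7 of 41 members lower and 4 higher, with a median of -0.15 at percentile 0.14. Within cluster 2 only 1 member was lower and 0 higher, with a median of -0.08 at percentile 0.26. In the class, the lowest were Epha7, an ephrin receptor gene, at -0.99 (-1.09 to -0.90) and Sema6d at -0.90 (-1.02 to -0.79). The highest were Cdh13 at 1.25 (1.18 to 1.32) and Tenm4 at 1.02 (0.94 to 1.10). Neurexins and their partners had 0 of 11 members past 1.5-fold and a median of -0.10 at percentile 10.17.

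Extracellular matrix genes and matrix proteases, named in the study's title, had medians inside the random range. Matrix genes had 1 of 17 members higher and 1 lower, with a median of 0.10 at percentile 79.38. They were the proteoglycan genes Spock1 at 0.59 (0.38 to 0.80) and Spock3 at -0.61 (-0.73 to -0.49). Proteases and their inhibitors had 4 of 16 members higher and 1 lower, with a median of 0.01 at percentile 34.29. The metalloprotease genes Adamts18 and Adamts9 were at 1.51 (1.09 to 1.93) and 1.41 (1.10 to 1.71), and Mmp17 at -0.60 (-0.89 to -0.31). Within cluster 2 the matrix list had 1 member higher and 0 lower, and the protease list 3 and 0.

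Synaptic and channel genes had list medians inside the random range. Synaptic vesicle release genes had 0 of 27 members past 1.5-fold, with a median of -0.02 at percentile 29.46. Postsynaptic density and CaMK signalling genes had 1 of 30 higher, Lrrtm1 at 1.00 (0.58 to 1.40), with a median of 0.05 at percentile 85.22. Glutamate receptor genes had 2 of 21 higher, Grik4 at 0.87 (0.77 to 0.96) and Grin3a at 0.78 (0.58 to 0.98), and 1 lower, Grm3 at -1.04 (-1.30 to -0.79), with a median of -0.01 at percentile 55.73. GABA and glycine receptor genes had 1 of 15 lower, Glra2 at -0.75 (-1.17 to -0.35), with a median of -0.02 at percentile 30.8. Potassium channel genes had 2 of 27 higher, Kcnn3 at 0.77 and Kcnd3 at 0.60, and 2 lower, Kcnt2 at -0.83 and Kcnk1 at -0.69, with a median of -0.05 at percentile 11.54. Sodium and calcium channel genes had 2 of 22 higher, Cacna1g at 1.03 and Cacna1i at 0.72, with a median of 0.03 at percentile 65.64. Within cluster 2 the glutamate receptor, potassium channel and postsynaptic lists had 0 members past 1.5-fold, with Grik4 at 0.51 (0.39 to 0.64), Grin3a at 0.16 (-0.08 to 0.39) and Grm3 at -0.55 (-0.89 to -0.23), while GABA and glycine receptors had 1 lower and sodium and calcium channels 1 higher.

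Of the remaining lists, trophic factor and neuropeptide genes had 2 of 13 members higher, Vegfa at 0.68 (-0.03 to 1.34) and Ntf3 at 0.65 (0.44 to 0.86), with a median of -0.02 at percentile 49.4. Heat shock and stress genes had 1 of 9 higher, Dnaja1 at 0.60 (0.20 to 0.97), with a median of 0.01 at percentile 22.02. Within cluster 2 these lists each had 1 member higher and 0 lower. Chromatin and transcription regulators had 0 of 22 past 1.5-fold and a median of 0.11 at percentile 91.47. The IL-33 receptor gene Il1rap was at -0.17 (-0.25 to -0.09), with Il33 the only other member above the floor. Of interferon genes 2 were above it, too few for a median, among them Stat2 at 0.40 (-0.06 to 0.84).

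Markers of other cell types and of cytoplasmic RNA were read in the same nuclei. Interneuron markers had 0 of 5 past 1.5-fold and a median of -0.24 at percentile 1.67. CA pyramidal markers had 1 of 7 higher, Rgs14 at 0.82 (0.37 to 1.25), with a median of -0.09 at percentile 13.06, and 0 past 1.5-fold within cluster 2. Astrocyte markers had 0 of 4 past 1.5-fold and a median of 0.04 at percentile 54.44. Of oligodendrocyte markers only Mbp at 0.30 (0.08 to 0.51) and St18 at -0.44 (-0.62 to -0.27) were above the floor, and of microglia markers 0 were, with 14 enriched and 37 control UMIs of Cx3cr1. Ribosomal protein genes, whose reads can be shared with pseudogene copies, had 1 of 33 higher and 3 lower, with a median of -0.12 at percentile 0.1, which became 0.13 among nuclei with at least 1500 genes. Mitochondrial genes had 1 of 11 higher, mt-Nd3 at 0.81 (0.31 to 1.29), with a median of 0.15 at percentile 87.47. Of the sex-linked genes, Xist, the RNA of the inactive X chromosome, was at 1.15 (1.10 to 1.2) and Tsix at 1.44 (1.05 to 1.83), while the Y-linked Uty was at -0.68 (-0.99 to -0.38), Kdm5d at -0.73 (-1.31 to -0.20), Eif2s3y at -0.33 (-0.65 to -0.02) and Ddx3y at -0.27 (-0.82 to 0.24).

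**Figure D4:**
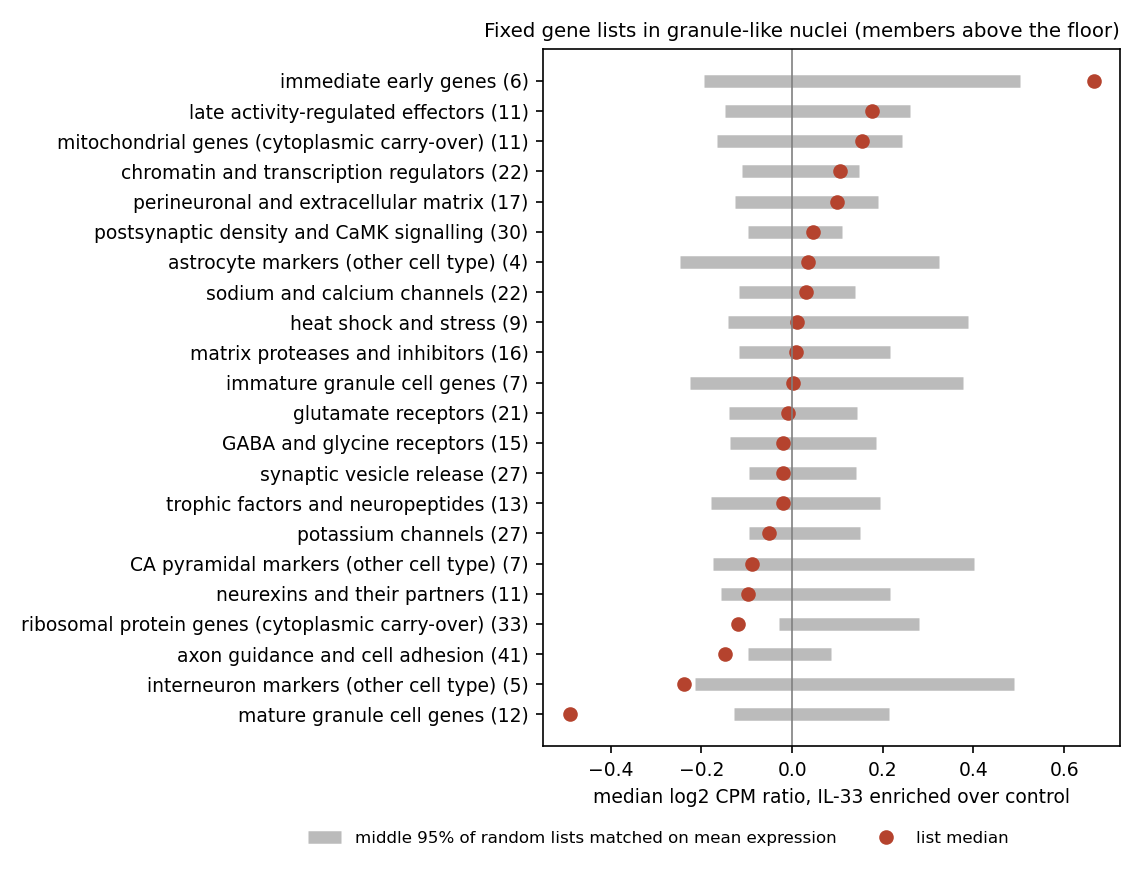
Median log2 CPM ratio (IL-33 enriched over control) of each fixed gene list in granule-like nuclei (points), with the middle 95% of random lists matched on mean expression (grey bars) and the number of members above the floor in parentheses. Immediate early genes at 0.67 lie above their bar, and mature granule cell genes at -0.49, axon guidance and cell adhesion genes at -0.15, ribosomal protein genes at -0.12 and interneuron markers at -0.24 lie below theirs.

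CA1 pyramidal-like nuclei, the only other class with at least 50 nuclei in each library, were compared in the same way. Maml3, a coactivator of Notch signalling, was 2.61 times as high in the enriched library (1.94 to 3.46), Ttc28 2.51 times (1.66 to 3.68) and the myosin gene Myo5b 2.47 times (1.64 to 3.59). Rnf115, a ubiquitin ligase gene, was at a log2 ratio of -1.24 (-2.02 to -0.55), the transcription factor gene Dach1 at -1.19 (-2.04 to -0.46) and the adhesion gene Sdk1 at -1.14 (-1.88 to -0.49). Of 3366 genes above the floor, 126 were at least 1.5-fold higher and 68 lower, from 94 enriched and 2208 control nuclei. Counting noise at these depths gave a median of 30.5 higher and 34 lower. The parts of the control, which are deeper at 4149015 and 2458325 UMIs, differed at 7 and 11 genes, so these counts cannot be set against those between the libraries. The split became 63 higher and 152 lower with TMM scaling and 64 and 148 with median-of-ratios scaling. Without doublet removal, where all nuclei were clustered anew, 225 genes were higher.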

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

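No paired analysis was possible because each group had 1 library. Of the settings, at least 1500 genes a nucleus, at least 3 Xist UMIs, at least 4 Xist UMIs in both libraries, Xist with no Y-linked UMI in both, and weighted clusters were chosen after seeing the data. The Il33 ratio in granule-like nuclei ranged from 1.18 with weighted clusters to 4.02. Under every setting run for them, the Il33 ratio between control granule-like clusters stayed between 3.05 and 7.71, the immediate early list median between 0.53 and 0.76 and the interneuron marker median between -0.37 and -0.02. The granule-like share stayed above the control's, at 56.1% to 82.4% against 11.3% to 38.4%. A minimum of 800 genes, the rule for Xist-negative nuclei and the nuclei of the joint table left the nuclei as they were. Thinning, a floor of 50, the Y-positive part of the control, 1500 genes and Xist with no Y-linked UMI in both left fewer than 3 immediate early genes above the floor, so no median was given. Resolution 0.4 and 1500 genes gave 1 granule-like cluster, so no cluster shares. With 34 Il33 UMIs in enriched granule-like nuclei and 94 enriched CA1 nuclei, depth limits the Il33 ratios and all CA1 counts.

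The shares given are of granule-like and CA1 pyramidal-like nuclei in each library and of granule-like nuclei in the cluster that held most enriched ones. With the Xist-positive control the control shares were 35.7% granule-like and 19.8% CA1, and with its Y-positive part 28.6% and 24.6%, with Il33 at 3.46 CPM in the control and a ratio of 4.02. Without doublet removal, where all nuclei were clustered anew, CA1 was 11.9% of the enriched library and 23.2% of the control, and 225 CA1 genes were higher. The 5 enriched doublets are too few to give that rise from 8.75%, so other enriched nuclei changed class. At resolution 0.4 CA1 was 19.4% of the control, and at 1.5 the main cluster held 86.2% of enriched and 22.3% of control granule-like nuclei. With clusters from the control alone CA1 was 11.1% and 23.6%, and the main cluster held 83.45% and 24.96%. The cause of these shifts was not tested.

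Gene counts are given as higher and lower. Thinning gave 50 and 41 in CA1, from fewer UMIs. TMM scaling gave 343 and 409 in granule-like and 63 and 152 in CA1 nuclei, with the axon guidance median at -0.28. Median-of-ratios scaling gave 336 and 416, 64 and 148, and a median of -0.28. A floor of 50 gave 264 and 104 in granule-like and 21 and 20 in CA1 nuclei, no floor 3416 and 1294, and 3081 and 1393, and a 2-fold rule 124 and 31, and 18 and 4. These follow from the number of genes counted, the log2 shift or the size the rule asks for.

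Nuclei with at least 1500 genes were 56.1% and 11.3% granule-like and 13.9% and 29.0% CA1 in the enriched and control libraries. There 351 granule-like and 78 CA1 genes were higher, the axon guidance median was -0.052, and the ribosomal protein gene median turned to 0.13. With at least 3 Xist UMIs the enriched library was 82.3% granule-like, 92.7% of them in the main cluster. With Xist and no Y-linked UMI in both, granule-like shares were 82.2% and 35.7%, CA1 shares 6.61% and 19.8%, and 67 CA1 genes were higher. With at least 4 Xist UMIs in both, granule-like shares were 82.4% and 38.4%, the control CA1 share 19.5%, and the main cluster held 92.7% and 30.8%. With weighted clusters Il33 in control granule-like nuclei was 11.8 CPM and its ratio 1.18, the mature granule median was -0.15, and the log2 ratios of Clmp (0.39), Syt7 (0.048), Gabra5 (0.00), Dpysl3 (-0.009) and Neurod2 (0.17) turned, which the weighting shows to rest on the cluster mix. The cause of the other shifts was not tested. Of the values of 108 named genes across settings, 1474 stayed within the interval of the main value and 141 moved beyond it. Another 5 turned, which was counted only for genes whose main interval left out no change. Turns of genes with wider intervals are among the other values.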

Other observations

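Of the tests in this part, those of a separate enriched cluster, of the sort, of free RNA, of male nuclei and of the cluster mix were chosen only after the result was seen. Matrix protease genes were read again within granule-like cluster 2, where 3 of 16 members were at least 1.5-fold higher in the enriched library and 0 lower, with a list median of 0.03 at percentile 49.02. They were Mmp24 at a log2 ratio of 0.67 (95% interval 0.29 to 1.06), Adamts18 at 0.62 (0.13 to 1.11) and Adamts9 at 0.59 (0.23 to 0.95). Among matrix genes in cluster 2, Lama2 was at 0.60 (-0.31 to 1.52), Spock3 at -0.44 (-0.59 to -0.29) and Tnr, an abundant gene of perineuronal nets, at 0.06 (-0.01 to 0.14). In the control library alone, Il33 was 7.53 CPM (2.44 to 17.6; 5 UMIs) in CA2 pyramidal-like nuclei, 2.69 (1.47 to 4.51) in CA3, 2.08 (1.29 to 3.19) in CA1 and 1.12 (0.364 to 2.62) in GABA interneuron-like nuclei. Cluster 9, which matched no class and was led by L3mbtl4, Bace2 and Gpc3, was 5.96% (4.62 to 7.55) of the enriched library and 3.64% (3.29 to 4.02) of the control.

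Most enriched granule-like nuclei lay in cluster 2. With clusters made from control nuclei alone, 83.45% of enriched granule-like nuclei still fell in 1 cluster that held 24.96% of control ones. Such a cluster therefore forms without the enriched library. Each enriched nucleus took the cluster of its nearest control nuclei, so a shift shared by the whole enriched library could also place them together. The values cannot tell such a shift from a kind of granule neuron. A candidate explanation is that the sort collected granule neurons of a kind with more Il33: inside the control library, Il33 was 4.49 times as high in cluster 2 (2.51 to 8.23) as in other granule-like nuclei, with Il33 left out of the clustering. A dissection that took more of 1 end of the hippocampus stays open. Wfs1, a dorsal CA1 gene, was at a log2 ratio of 0.66 (-0.32 to 1.51) in CA1 pyramidal-like nuclei and the ventral gene Dcn at -0.09 (-0.92 to 0.63). These are too few counts to decide, and they cover CA1 only. Inside the control, cluster 2 lay above other granule-like nuclei for Trhr (log2 ratio 2.66) and Nr2f2 (2.55) and below them for Lct (-2.03). Whether these genes mark position along the hippocampus was not tested. The reporter genotype and the animal or animals behind the library stay among the open explanations, untested.

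Y-linked UMIs were seen in 32.4% (29.6 to 35.3) of the enriched nuclei used, all of which had Xist. Free RNA as the whole cause was argued against, since Y-linked CPM was 1.94 times as high (1.56 to 2.39) in nuclei with 2 Xist UMIs as in those with 3 or more, and the former were deeper (medians 3421 and 2928 UMIs), where a like amount of free RNA would be a smaller share. Male nuclei left in the file as the whole cause were argued against, since nuclei with 6 or more Xist UMIs had 0.451 times (0.392 to 0.517) the Y-linked CPM of control nuclei without Xist. Control nuclei with 6 or more Xist UMIs also had Y-linked UMIs, at 61.0 CPM against 251.2 without Xist. Free RNA and male nuclei acting together were not tested and stay open. Y-linked CPM in nuclei with 6 or more Xist UMIs was 1.86 times the control's (1.57 to 2.19) in the enriched library. These enriched and control nuclei were 82.2% and 41.1% granule-like, so their class mix differed. Within granule-like nuclei Y-linked CPM was 1.63 times as high (1.30 to 2.04). The lower end of that interval fell short of the bound set beforehand. Reads of X-linked copies as the whole cause were therefore only weakly argued against. As a part of the cause they stay open: Ddx3y was 18.8% (17.0 to 20.7) of Ddx3y and Uty UMIs in control nuclei without Xist, which overlaps the 24.5% (16.7 to 33.8) of enriched nuclei with 6 or more Xist UMIs but not the 26.4% (20.9 to 32.4) of all enriched nuclei or the 26.8% (21.3 to 33.0) of control nuclei with 6 or more, and no biological explanation was tested.

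Immediate early genes were higher in enriched granule-like nuclei. The mix of granule-like clusters as the whole cause was only weakly argued against. With the control's clusters weighted as in the enriched library the list median was 0.641 against 0.665. The floor was applied again to the weighted counts, so these medians may rest on different members. Within cluster 2 the 4 members above the floor had a median of 0.33, inside the random range. Summed UMIs of all members were 1.43 times as high there (1.21 to 1.69). A difference in handling that reaches every class may contribute and cannot be told apart from one in activity: summed UMIs in CA1 pyramidal-like nuclei were 1.40 times as high (1.17 to 1.67), an interval whose lower end fell short of the bound set beforehand. Over all nuclei outside the granule-like class they were 1.61 times as high (1.43 to 1.81), which goes with such a difference but also with another mix of classes. Each library came from its own animals, so handling, animal and sort are confounded with the group.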
